A study of Mus musculus with 386 samples.

How the data were processed

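Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in 386 libraries from 97 mice. Per the labels, each library comes from 1 of 4 tissues (gonadal fat pad, pancreatic islets, liver or gastrocnemius muscle), 1 of 8 inbred founder strains, 1 of 2 sexes and 1 of 2 diets, with 10% or 44% of the energy from fat. Fat pad, liver and muscle are called adipose, liver and skeletal below. Per the labels' protocols, fat pad, liver and muscle were dissociated to single-cell suspensions and frozen before transposition, while islets rested overnight after isolation. Tissue, strain, sex, diet and replicate number were read from the sample labels, which also give an animal number that is shared by the tissues of 1 mouse. The replicates are therefore separate animals.

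For each library, the authors deposited a peak list and a table of read counts over the peaks of that same library. The submitters' processing notes name cutadapt 2.3, Bowtie2 2.3.5, deepTools and MACS2 2.2.7.1, and the builds GRCm38 and mm10; the step each tool was used for, duplicate removal and any shift of reads for the transposase offset are not given in the sources used here. The peak lists have the 10 columns of the narrowPeak format. In the deposited lists, the fold enrichment is a linear ratio of each peak over its local background, the p-value and q-value are given as −log10, and the integer score is a multiple of the −log10 q. The lowest −log10 q in the deposited lists was 1.30. The score was not used. The fold values are the authors' and served only to describe peaks, and the −log10 values served only to rank or filter peaks within a list. The deposited read counts are whole numbers that were not normalised. They exist only where a library has a peak, since peaks were called library by library, so a region without a peak has no count rather than a count of 0.

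Peaks of all libraries were merged into a catalogue of 185244 regions, each a stretch of mm10 covered by peaks of at least 10 libraries (30 in an alternative). A region was detected in a library if a deposited peak of that library overlapped it by at least 1 bp. Coordinates are 1-based mm10 positions. Regions were linked to the protein-coding gene that contains them, otherwise to the nearest one within 50 kb, with a RefSeq table of GRCm38.p6 that lists 49997 genes. The fixed plan linked regions to the nearest transcription start; the table gives no strand, so gene bounds were used instead, and a region within 1 kb of either end of a gene is called a gene end region. Gene end regions made up 10.5% of the catalogue, regions inside genes 45.5%, regions outside genes but within 50 kb 23.3%, and regions farther from any gene 20.7%.

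Detection was tested with limma 3.58.1 in R 4.3.3, as a linear model of presence (1) or absence (0) in each library, with Benjamini-Hochberg adjustment over all regions tested in a tissue and a threshold of 0.05. Only regions detected in at least 10 and missed in at least 10 libraries of a tissue were tested. Models for sex and diet held strain, sex, diet, library run and the log2 peak number of the library. Library run means a block of serial numbers in the library names, separated by a gap of at least 100; it gave 9 runs of 4 to 92 libraries that are unbalanced over strains, so strain models left it out. A strain difference is the strain minus the mean of the other 7 strains. Interactions were tested by adding sex by diet or strain by diet terms. A region was called restricted to a tissue if its detection share exceeded that in each of the other 3 tissues by at least 50% of libraries, with an adjusted p under the threshold against each. Differences in detection are given in percentage points as fitted by the model, with their SE, beside the raw counts of libraries; fitted values can exceed the raw ones because of the covariates.

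Read counts were tested with the quasi-likelihood test of edgeR 4.0.16 after TMM normalisation, on regions with a peak in every library used, which are the more open regions. Libraries under 0.5 of their tissue's median peak number were left out of these fits, leaving 91 adipose, 96 islet, 97 liver and 93 skeletal libraries and 15597, 16384, 12912 and 9032 regions. Those regions held 995638 to 16785301 reads per library. DESeq2 1.42.0 was the alternative tool. Levels are given as CPM, the count scaled by the reads a library has in these regions.

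Gene lists for cell types, metabolic pathways, sex chromosome genes and type 2 diabetes loci, 34 in all with 576 genes, were fixed before the data were examined, as were the main tests, most alternatives to them and the rule for naming regions. The counts without doubted libraries and the list tests on read counts were chosen after seeing the data. All 576 genes matched the annotation and 538 had a region. Lists were compared with all other regions by camera in limma with a preset correlation of 0.01, and again with an estimated correlation. The marker share of a library is the fraction of the gene end regions of a cell type list that were detected in it. Named regions follow this rule: for sex and diet, the 6 largest detection differences in each direction per tissue, 1 region per gene, with X and Y regions described apart, and the 5 largest log2 fold changes in each direction for read counts; for strain, the 3 highest F statistics per tissue and the largest difference of each strain; for tissue, the 5 largest margins; for interactions, the 3 smallest p-values; then list members past the threshold, at most 4 per list and direction. Not every region the rule selected is printed.

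Differences in peak number were tested with permutation tests of 100000 resamples within strata of the other factors, 2-sided, over a family of 40 tests. The models were tested on simulated data. In simulated liver detection with a sex difference of 0.3, 0.5 or 0.7, limma recovered 13 of 67, 59 of 67 and 66 of 66 regions, with 9 false calls among 147. For diet it recovered 8 of 67, 56 of 67 and 66 of 66, with 10 false calls among 140. For regions with 1 strain apart, the F-test over the 8 strains recovered 21 of 100 at a difference of 0.5 and 64 of 100 at 0.7. There were 7 false calls among 92. At each size 100 of 45397 regions were changed, while 29125 of 48439 real liver regions were called by strain. The strain rates therefore need not hold for the real fits, and the test of each strain against the others was not simulated. For read counts, edgeR recovered 56 of 67 regions at a log2 sex difference of 0.2 and all 67 at 0.4. So a detection difference of 0.3 between the sexes or diets, or of 0.5 for 1 strain by the F-test, was mostly missed in these simulations.

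The animal number pairs the tissues. Over 56600 regions, the median correlation of the deviations of same-animal libraries from their group means lay between -0.003 and 0.006 in the 6 pairs of tissues, so pairing carried little. With the animal as a block, the counts of restricted regions were 1004 for adipose, 26011 for islet, 2535 for liver and 37 for skeletal.

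Alternatives tried were a stricter −log10 q of 4, an overlap of at least 0.5 of the region, only the 15000 strongest peaks of each library, other covariates, a Cochran-Mantel-Haenszel test, an offset for the covered length of each region, links within 10 kb, leaving out libraries with few peaks, and leaving out each replicate. Computations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Expression, genotype and physiological data of these mice were not used here.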

Results

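Open chromatin was compared in 386 ATAC-seq libraries from 97 mice of 8 inbred strains, in gonadal fat (97 libraries), pancreatic islets (96), liver (97) and gastrocnemius muscle (96). Each strain was represented by both sexes on diets with 10% or 44% fat, with 3 animals in most of the 128 groups of tissue, strain, sex and diet. The strains were A/J, C57BL/6J, CAST/EiJ, NOD/ShiLtJ, NZO/HlLtJ, PWK/PhJ, WSB/EiJ and the eighth strain, whose label begins with digits and is given in full in the plots of peaks and of strain regions. The questions addressed are where accessible regions differ between tissues, strains, sexes and diets, and which of them lie near genes of metabolic disease.

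Islet libraries had the most peaks, 64252 ± 10042 (SD, n = 96), and muscle libraries the fewest, 32067 ± 10742 (SD, n = 96). Adipose libraries had 55707 ± 14704 peaks (SD, n = 97) and liver libraries 43464 ± 8799 (SD, n = 97). The median number of reads in peaks was 9954673 in adipose (range 2559754 to 23452569), 9301683.5 in islet (range 4087798 to 26706572), 7408404 in liver (range 2276271 to 18262415) and 3503171 in muscle (range 687063 to 13199202). Of 40 permutation tests of the peak number, each 2-sided, 4 passed an adjusted p of 0.05. Female adipose libraries had fewer peaks (49112 ± 13862, SD, n = 48) than male ones (62166 ± 12578, SD, n = 49), at the smallest p the permutations can give, 1e-05 (adjusted p = 0.0004). C57BL/6J libraries had more peaks than the other strains in adipose (66341 ± 7461, SD, n = 12; adjusted p = 0.0284) and fewer in liver (34484 ± 4892, SD, n = 12; adjusted p = 0.001). PWK/PhJ libraries had more peaks in liver (50762 ± 6749, SD, n = 12; adjusted p = 0.0164).

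**Figure D1:**
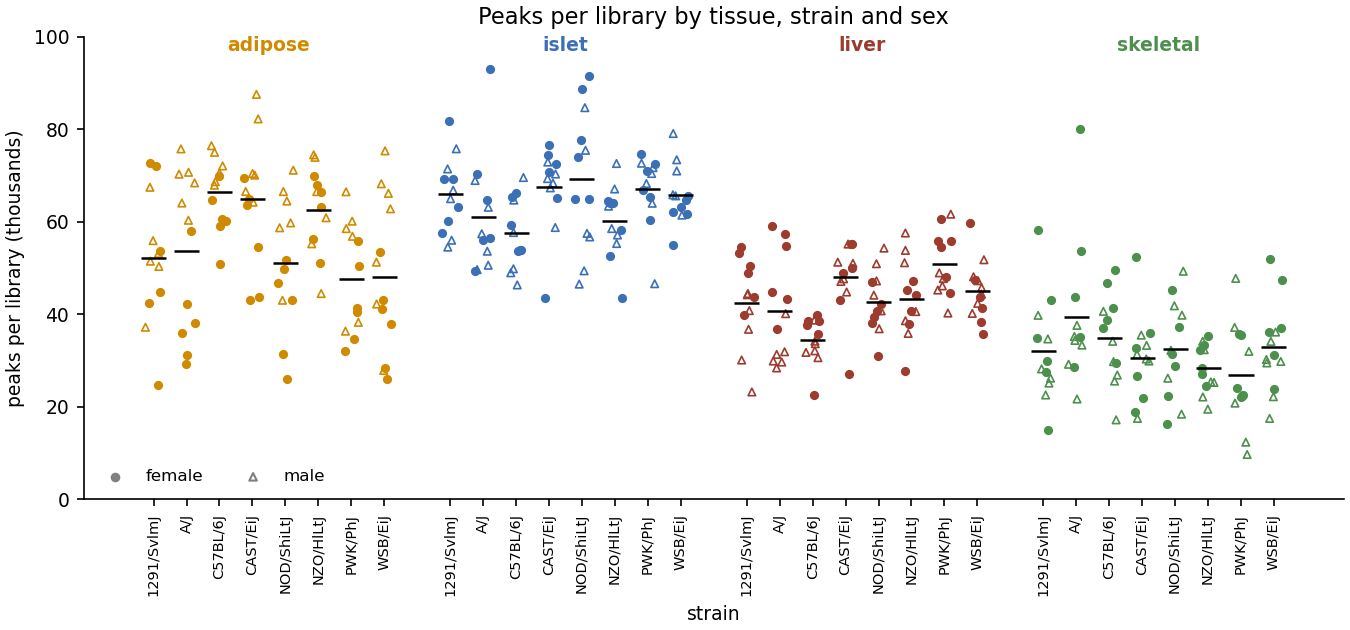
Peaks per library, in units of 1000 peaks, by tissue and strain; each point is a library (filled, female; open, male) and each bar is the mean of a strain. Female adipose libraries average 49112 peaks and male ones 62166.

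The Y-linked genes Eif2s3y, Uty and Ddx3y served to check the sex labels. A region at Eif2s3y (Y:1009910-1010980) was detected in 192 of 195 male and 2 of 191 female libraries, and regions at Uty (Y:1244762-1246347) and Ddx3y (Y:1285594-1287024) in 191 of 195 male and 2 of 191 female libraries. In adipose, the library labelled female 44% replicate 3 of the eighth strain had all 3 regions, and the library labelled male 44% replicate 2 of that strain had 0 of them. In liver, the library labelled male PWK/PhJ 10% replicate 1 had 0, and the library labelled female 10% replicate 2 of the eighth strain had all 3. A pair of male PWK/PhJ 44% muscle libraries had 1 and 0 of the 3, at 12339 and 9672 peaks. The labels were kept, and counts without the libraries whose Y regions or cell markers were out of place (2 in adipose, 2 in islet, 2 in liver and 9 in muscle) are given beside the main ones. The nearest library by detection was of the same tissue for 385 of 386 libraries.

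Markers of the cells that each tissue is named for were open in islet but seldom in liver and muscle. Islet beta cell genes had a marker share of 0.786 ± 0.103 (SD, n = 96) in islet libraries and at most 0.246 ± 0.0755 (SD, n = 97, adipose) in the others. Regions of Ins1, which encodes insulin, and of G6pc2 were each detected in 95 of 96 islet libraries and in 0 libraries of the other tissues, and regions of Ucn3 in 96 of 96 and 0. Hepatocyte genes had a share of 0.184 ± 0.0694 (SD, n = 97) in liver and 0.614 ± 0.135 (SD, n = 96) in islet. A region of the albumin gene Alb was detected in 8 of 97 liver and 95 of 96 islet libraries, and one of Tat in 0 liver and 96 islet libraries. In liver, the endothelial share was 0.725 ± 0.0871, the lymphocyte share 0.583 ± 0.151 and the macrophage share 0.522 ± 0.178 (SD, n = 97). The liver sinusoidal endothelial genes Stab2 and Clec4g had a region in 97 of 97 liver libraries.

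In muscle, the myofibre share was 0.270 ± 0.137 (SD, n = 96), below that in adipose, 0.525 ± 0.158 (SD, n = 97), while the fibroblast share was 0.542 ± 0.170 and the endothelial share 0.479 ± 0.156 (SD, n = 96). A region of the muscle creatine kinase gene Ckm was detected in 52 of 96 muscle libraries and in 96 libraries of each other tissue. In adipose, the white adipocyte share was 0.80 ± 0.0786, the fibroblast share 0.706 ± 0.130 and the macrophage share 0.561 ± 0.155 (SD, n = 97). Plin1, which encodes the coat protein of lipid droplets, had a region in 97 of 97 adipose and 97 of 97 liver libraries, and the white adipocyte share in liver was 0.756 ± 0.0861 (SD, n = 97). The acinar share in islet was 0.285 ± 0.179 (SD, n = 96), and it reached 0.867 and 0.933 in male NZO/HlLtJ 44% replicates 1 and 3, against at most 0.8 in the other islet libraries. The lymphocyte share was 0.632 to 0.947 in 9 muscle libraries, against at most 0.474 in the rest.

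**Figure D2:**
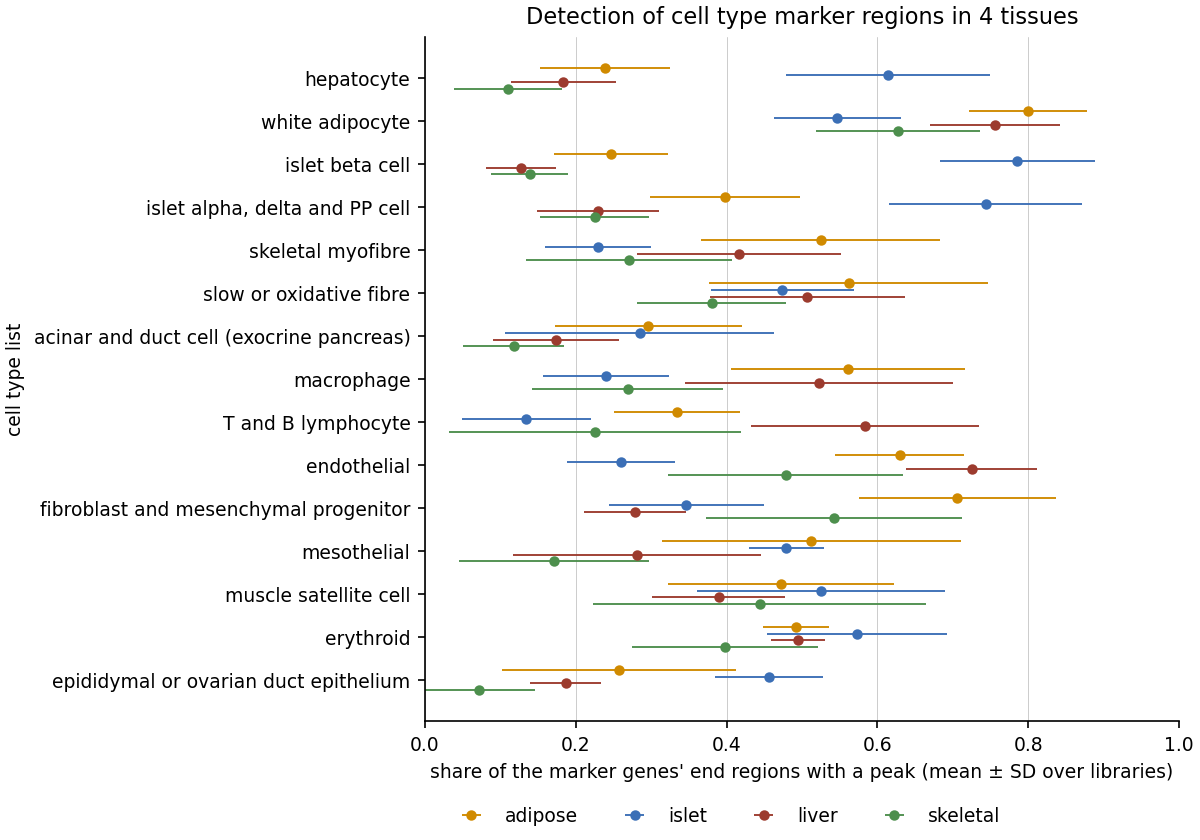
Share of the gene end regions of each of 15 cell type lists that had a peak (fraction of regions; mean with SD over libraries) in adipose (n = 97), islet (n = 96), liver (n = 97) and muscle (n = 96). Hepatocyte regions were detected at a share of 0.184 in liver and 0.614 in islet.

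Islet had the most restricted regions, 26015 of 174877 tested, against 2534 in liver, 1001 in adipose and 37 in muscle. Without the doubted libraries the counts were 26108, 2578, 950 and 48. With only the 15000 strongest peaks of each library, they were 4993, 1023, 22 and 250, so islet still had the most but adipose had fewer than muscle. The tissue model did not hold the peak number, which was highest in islet and lowest in muscle. Tissue also went with preparation, since islets rested overnight and the other tissues were frozen as suspensions. The counts cannot be told apart from preparation. Of the islet regions that tie at a margin of 100.0 percentage points, the 5 named here were taken by position. They lie inside Xkr4 (1:3360638-3361705), Rgs20 (1:4970128-4971428), St18 (1:6509933-6511466), Sntg1 (1:9208239-9210582) and Ppp1r42 (1:9985417-9986431), each detected in 96 of 96 islet libraries and 0 libraries of the other tissues. St18 encodes a zinc finger transcription factor. In liver, regions inside Shisa9 (16:12233231-12235056) and near Slc9a9 (9:94645193-94646310) were detected in 97 of 97 libraries and 0 elsewhere. Regions inside the endothelial scavenger receptor gene Stab2 (10:86992266-86993416), near the lectin gene Cd209a (8:3736551-3737809) and at the end of Oit3 (10:59441429-59443724) were detected in 97 liver libraries and 1 library elsewhere.

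In adipose, a region inside Rab32 (10:10546210-10547202) was detected in 89 of 97 libraries, against 6 of 96 islet, 0 liver and 2 muscle libraries, a margin of 85.5 percentage points (largest adjusted p = 7.37e-102). A region near the integrin gene Itgb3 (11:104599126-104600029) was detected in 83 adipose and at most 5 libraries of another tissue. In muscle, a region near Dio2 (12:90698895-90699737), which encodes an enzyme that activates thyroid hormone, was detected in 70 of 96 libraries and 1 library elsewhere, a margin of 72.0 percentage points (largest adjusted p = 2.48e-67). Of the restricted regions, 4.24% lay at gene ends in islet, 5.33% in liver, 10.2% in adipose and 2.7% in muscle.

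Each tissue was then compared with the mean of the other 3 for the fixed lists. Of 118 beta cell regions, 106 were higher in islet and 8 lower (106 and 8 adjusted over the list alone; camera adjusted p = 2.69e-14), and 55 were restricted to islet; this call held with an estimated correlation (adjusted p = 0.00392). Of 127 regions of alpha, delta and PP cell genes, 105 were higher in islet and 12 lower (105 and 12 adjusted over the list alone; adjusted p = 1.04e-06, and adjusted p = 0.186 with an estimated correlation). Of 378 insulin secretion regions, 269 were higher and 73 lower (269 and 73 adjusted over the list alone; adjusted p = 3.37e-05, and adjusted p = 0.209 with an estimated correlation). Endothelial regions went the other way in islet, with 29 of 220 higher and 153 lower (29 and 152 adjusted over the list alone; adjusted p = 7.33e-08, and adjusted p = 0.139 with an estimated correlation).

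In liver, 122 of 220 endothelial regions were higher and 55 lower (122 and 56 adjusted over the list alone; adjusted p = 4.23e-08, and adjusted p = 0.106 with an estimated correlation). Of 158 lymphocyte regions, 86 were higher in liver and 40 lower (86 and 40 adjusted over the list alone; adjusted p = 6.16e-06, and adjusted p = 0.472 with an estimated correlation). Of 82 hepatocyte regions, 15 were higher in liver and 56 lower (15 and 57 adjusted over the list alone; adjusted p = 0.0241, and adjusted p = 0.507 with an estimated correlation), and 0 were restricted to liver against 25 to islet.

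In adipose, 61 of 96 white adipocyte regions were higher and 22 lower (63 and 24 adjusted over the list alone; adjusted p = 0.00394, and adjusted p = 0.483 with an estimated correlation). Of 154 macrophage regions, 97 were higher in adipose and 18 lower (97 and 18 adjusted over the list alone; adjusted p = 0.00549, and adjusted p = 0.488 with an estimated correlation). Beta cell regions were lower in adipose, 91 of 118 against 11 higher (92 and 11 adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 0.0209). In muscle, 33 of 48 myofibre regions were lower and 3 higher (33 and 3 adjusted over the list alone), which did not differ from other regions (camera adjusted p = 0.886). Of 230 regions of matrix and fibrosis genes, 63 were higher in muscle and 92 lower (63 and 89 adjusted over the list alone); their median and mean difference were negative while camera ranked them above other regions (adjusted p = 5.39e-06, and adjusted p = 0.347 with an estimated correlation).

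At genes of type 2 diabetes loci, 254 of 1508 regions tested were restricted to islet (16.8%, against 14.9% of all regions), in 60 genes. Cdkal1 and Pam had 19 such regions each, Dgkb 15, Glis3 14 and Ube2e2 13, while Abcc8, Cobll1 and Slc30a8 had 9 each. Abcc8 encodes a subunit of the potassium channel that sulphonylureas close, and Slc30a8 the zinc transporter of insulin granules. In adipose 10 regions in 10 genes were restricted (0.663%), in liver 11 in 9 genes (0.729%, against 1.45% of all regions), and in muscle 0. As a list, the loci did not stand apart from other regions in islet, with 658 higher and 615 lower (camera adjusted p = 0.982).

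Between the sexes, adipose had the most regions that differed in detection, 3400 of 70290 tested, of which 1273 were higher in females and the rest lower. The gonadal fat pad lies by a different organ in each sex, so sex and the site of the pad cannot be told apart in adipose. Without the peak number in the model, 7744 differed and 959 of them were higher in females, so the split depends on how the lower peak number of female adipose libraries is treated. Without the doubted libraries 4107 regions differed. A region at the end of Cntn1 (15:92050872-92052272), which encodes a neural cell adhesion protein, was detected in 38 of 48 female and 7 of 49 male libraries, a fitted difference of 84.3 ± 7.67 percentage points (SE, adjusted p = 2.72e-14). A region near Batf (12:85725357-85726073), a transcription factor gene of lymphocytes, was detected in 30 of 48 female and 7 of 49 male libraries (78.4 ± 8.99, SE, adjusted p = 4.13e-10). A region inside Pkhd1 (1:20069605-20070348), an epithelial cilium gene, was detected in 37 of 48 and 6 of 49 (75.1 ± 8.87, SE, adjusted p = 1.2e-09). In the other direction, a region near Gdap2 (3:100224871-100226194) was detected in 3 of 48 female and 44 of 49 male libraries (adjusted p = 6.57e-16), one inside Klhl29 (12:5267682-5268639) in 2 and 38 (adjusted p = 3.77e-13), and one at the end of Eri2 (7:119783159-119783922) in 2 and 40 (-69.6 ± 6.29, SE, adjusted p = 2.15e-14).

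Among list genes in adipose, regions of the hormone receptor genes Pgr (33 of 48 female and 13 of 49 male libraries; 55.2 ± 10.5, SE, adjusted p = 0.000181) and Esr1 (43 and 29; 41.2 ± 8.38, SE, adjusted p = 0.000578) were higher in females. A region of Kdr, which encodes a vascular growth factor receptor, was detected in 26 female and 3 male libraries (62.9 ± 9.23, SE, adjusted p = 7.77e-07). Regions of Twist2 (3 and 39), Cacna1d (6 and 45), Hnf4a (2 and 31), Sox9 (4 and 29), Fto (11 and 44) and Wfs1 (13 and 45) were higher in males, with adjusted p-values of 1.49e-08, 3.08e-11, 5.94e-05, 8.93e-05, 2.18e-06 and 2.02e-06. A region of Pax8, which marks reproductive duct epithelium, was detected in 0 female and 19 male libraries (-33.0 ± 7.18, SE, adjusted p = 0.00143). For insulin secretion genes 2 of 125 regions were higher and 12 lower in females (15 lower adjusted over the list alone), without a difference from other regions (camera adjusted p = 0.479).

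**Figure D3:**
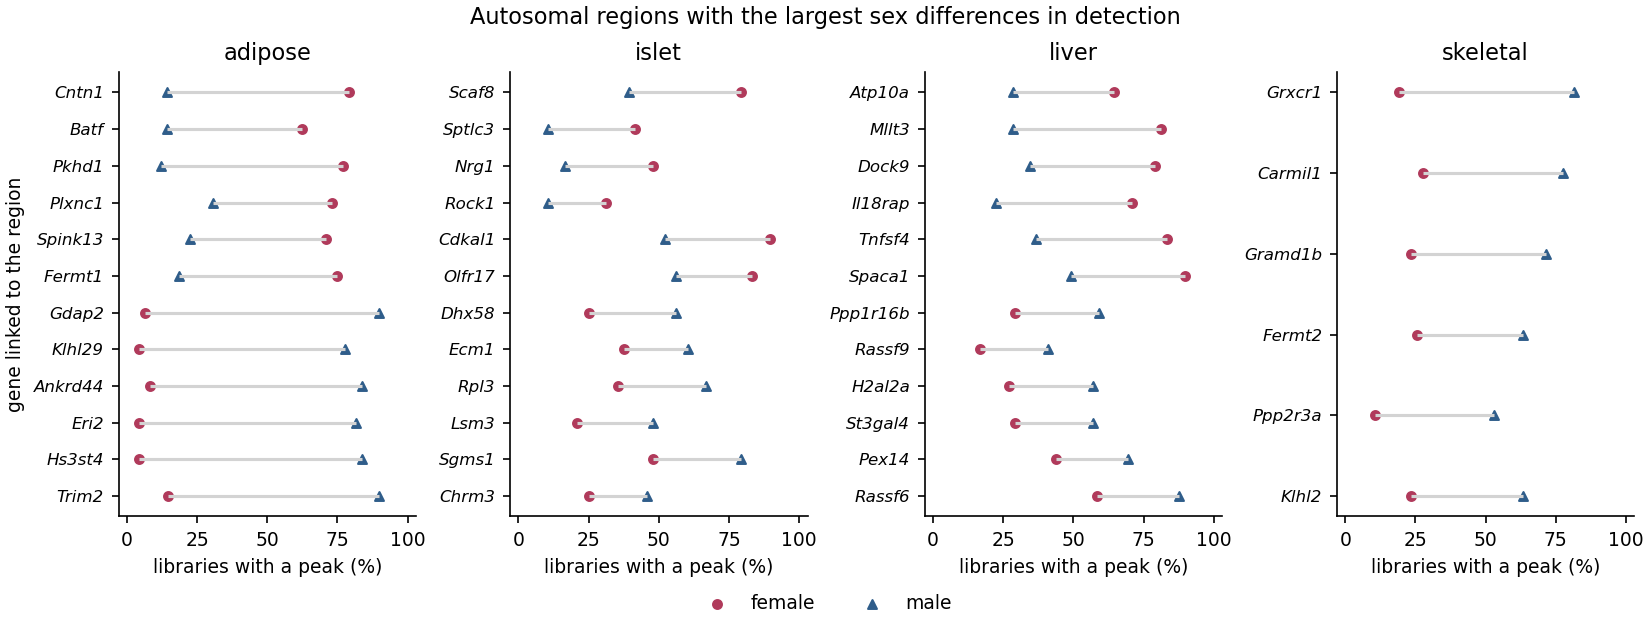
Percent of female and of male libraries with a peak in the autosomal regions with the largest sex differences, in 4 panels for the 4 tissues. In adipose the Cntn1 region was detected in 38 of 48 female and 7 of 49 male libraries.

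The other tissues had far fewer autosomal regions that differed by sex in detection: 31 of the 153 called in islet, 90 of 166 in liver and 68 of 104 in muscle. Without the doubted libraries the totals were 120, 245 and 104. Without the peak number, 111 of 133 were higher in females in islet, 125 of 146 in liver and 33 of 49 in muscle, against 118 of 153, 122 of 166 and 26 of 104 with it. In islet, a region near Scaf8 (17:3081432-3081972) was detected in 38 of 48 female and 19 of 48 male libraries (39.3 ± 7.85, SE, adjusted p = 0.00308), one near Cdkal1 (13:29871068-29871804) in 43 and 25, and one at the end of the viral RNA sensor gene Dhx58 (11:100701317-100704805) in 12 and 27 (-39.9 ± 9.32, SE, adjusted p = 0.0314).

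In liver, regions at the ends of the immune receptor and ligand genes Il18rap (1:40514911-40516150; 34 of 48 female and 11 of 49 male libraries; 42.6 ± 8.40, SE, adjusted p = 0.00274) and Tnfsf4 (1:161395073-161397023; 40 and 18; 42.3 ± 8.91, SE, adjusted p = 0.00696) were higher in females. A region of the X-linked Kupffer cell gene Vsig4 was detected in 45 female and 32 male libraries (32.3 ± 7.96, SE, adjusted p = 0.0401). A region at Ppp1r16b (2:158695830-158696808) was lower in females (14 and 29; -44.1 ± 8.78, SE, adjusted p = 0.00318). The list of female-biased liver genes had 0 of 55 regions called by limma (0 adjusted over the list alone; camera adjusted p = 0.796). In muscle all 68 autosomal regions called with the peak number in the model were lower in females. Female muscle libraries had 34756 ± 12275 peaks (SD, n = 47) and male ones 29487 ± 8374 (SD, n = 49, permutation test, adjusted p = 0.0686). As in adipose, the split by direction depends on how the peak number is treated. Over all chromosomes 104 regions were called in muscle, and 49 without the peak number in the model, of which 42 were among the 104. One at Grxcr1 (5:68086642-68087737) was detected in 9 of 47 female and 40 of 49 male libraries (-69.3 ± 8.61, SE, adjusted p = 9.25e-09), and one at the glucocorticoid target gene Fkbp5 in 23 and 37 (-41.4 ± 8.54, SE, adjusted p = 0.00479). Whether the sex differences of the tissues differ was tested apart.

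On the X chromosome, 130 of 137 called regions in adipose, 105 of 106 in islet, 67 of 67 in liver and 26 of 27 in muscle were higher in females. A region 40640 bp from Pls3 (X:75744334-75745013) was detected in 35 of 48 female and 1 of 49 male adipose libraries, 36 of 48 and 0 of 48 in islet, 30 of 48 and 0 of 49 in liver, and 35 of 47 and 0 of 49 in muscle. A region at Kdm6a (X:18177042-18178543), a histone demethylase gene, was detected in 36 of 48 female and 1 of 49 male liver libraries (66.7 ± 6.75, SE). In read counts, the region at X:18161644-18164173 of Kdm6a was higher in females by a log2 fold change of 0.90 ± 0.044 (SE) in adipose, 1.06 ± 0.029 in islet, 0.92 ± 0.048 in liver and 0.94 ± 0.033 in muscle. The list of X-inactivation and escape genes was higher in females in read counts of all 4 tissues, with 9 of 10, 9 of 13, 9 of 10 and 6 of 7 regions called (9, 9, 9 and 7 adjusted over the list alone), and with an estimated correlation too (adjusted p = 3.43e-08, 2.27e-14, 6.6e-11 and 2.67e-28).

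In read counts of regions open in every library used, 1804 of 15597 adipose regions differed by sex (834 higher and 970 lower in females), 507 higher and 219 lower among 16384 islet regions, 880 of 12912 liver regions (333 higher and 547 lower) and 24 of 9032 muscle regions (21 higher and 3 lower). With an offset for covered length, 341 of 448 were higher in adipose, 109 of 113 in islet, 26 of 1420 in liver and 7 of 7 in muscle, so the split by direction depends on this scaling. Without the doubted libraries the counts were 1889, 512, 1376 and 20, and DESeq2 called 2061, 941, 1087 and 30. In adipose (43 female and 48 male libraries), a region at Hoxa10 (6:52232220-52235066), a gene of posterior body identity, was higher in females by 0.76 ± 0.086 log2 (SE), with 43.6 ± 10.2 CPM (SD), and regions at Hoxa13 (6:52259060-52261248; 0.52 ± 0.092, SE, adjusted p = 5.12e-05) and near Hand2 (8:57327848-57329425; 0.58 ± 0.072, SE, adjusted p = 5.38e-09) were higher too. A region near Errfi1 (4:150870911-150872920), which encodes an inhibitor of EGF receptor signalling, was lower in females (-0.76 ± 0.084, SE; 20.3 ± 6.05 against 34.9 ± 10.9 CPM, SD; adjusted p = 1.17e-10).

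In islet (48 and 48 libraries), a region at the end of the potassium channel gene Kcna5 (6:126534482-126535992) was higher in females by 0.47 ± 0.079 log2 (SE), with 27.9 ± 12.9 against 19.6 ± 8.95 CPM (SD; adjusted p = 4.15e-05). A region of the proliferation gene Mki67 was higher in females (0.26 ± 0.054, SE, adjusted p = 0.00176). A region at the end of the beta cell transcription factor gene Pdx1 (5:147269910-147271576) was lower in females (-0.32 ± 0.069, SE; 31.8 ± 7.80 against 40.9 ± 13.4 CPM, SD), but not with the offset for covered length, under which the difference was 0.07. Of 12 regions of alpha, delta and PP cell genes 4 were higher in females (4 adjusted over the list alone; camera adjusted p = 0.0459, and adjusted p = 0.686 with an estimated correlation).

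In liver (48 and 49 libraries), endothelial genes stood out: 10 of 17 regions were lower in females (11 adjusted over the list alone; median log2 fold change -0.253; camera adjusted p = 2.12e-09, and adjusted p = 0.191 with an estimated correlation). They included regions of Kdr (-0.42 ± 0.087, SE; 40.7 ± 13.3 against 54.4 ± 17.8 CPM, SD; adjusted p = 0.00193), of the angiopoietin receptor gene Tek (-0.28 ± 0.075, SE, adjusted p = 0.0173), of Erg (-0.31 ± 0.075, SE, adjusted p = 0.0101) and of Sox17 (-0.29 ± 0.071, SE, adjusted p = 0.0108). A region at Wnt2 (6:17991110-17992218), a growth factor gene of central vein endothelium, was lower too (-0.46 ± 0.10, SE, adjusted p = 0.00486). The pan-leukocyte gene Ptprc had a region higher in females (0.31 ± 0.089, SE, adjusted p = 0.025), which the offset for covered length turned to -0.01. In muscle 4 autosomal regions were called, and those linked to Ndufab1, Uspl1 and Rabac1 were lower in females.

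Few regions were called by diet. In adipose, 12 of 70290 regions differed in detection, 11 of them higher at 44% fat, and 11 regions differed without the doubted libraries. At an unadjusted p under 0.05 limma gave 8446 adipose regions, which 2 of 100 groupings of the libraries reached, the real one included. The simulations in liver recovered 8 of 67 diet differences of 0.3, so few calls need not mean few changes. The Cochran-Mantel-Haenszel test called 0 in each tissue. A region at Npr1 (3:90451381-90452400), which encodes a natriuretic peptide receptor, rose from 13 of 49 libraries at 10% fat to 33 of 48 at 44% (38.5 ± 7.96 percentage points, SE). A region at Kirrel3 (9:34946761-34949081) rose from 16 to 34 libraries (40.5 ± 7.85, SE, adjusted p = 0.0398), and one near the interferon gene Ifnb1 (4:88530504-88531378) from 6 to 24 (42.0 ± 8.71, SE, adjusted p = 0.0466). A region at the end of Pax8 (2:24474738-24475771) went from 18 to 4 libraries (-33.6 ± 7.03, SE). In islet, liver and muscle limma called 0 regions, with 4466, 2319 and 1509 at an unadjusted p under 0.05.

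In adipose read counts (44 libraries at 44% fat and 47 at 10%), 29 of 15597 regions differed by diet, 16 higher and 13 lower at 44%; 34 differed without the doubted libraries. DESeq2 called 166, of which 96 were higher, and the offset for covered length 76, of which 0 were higher. A region at the hyaluronan synthase gene Has1 (17:17844652-17846320) was higher at 44% (0.40 ± 0.081 log2, SE; 23.2 ± 7.35 against 17.9 ± 6.90 CPM, SD). A region near the neutrophil chemokine gene Cxcl1 (5:90875803-90877346) was higher as well (0.28 ± 0.064, SE; 31.6 ± 9.75 against 26.7 ± 9.19 CPM, SD; adjusted p = 0.0413). Of 16 inflammation regions 1 was higher at 44% (5 adjusted over the list alone; camera adjusted p = 0.000191, and adjusted p = 0.209 with an estimated correlation). Among epididymal and ovarian duct genes, 1 of 32 regions was lower in detection (3 adjusted over the list alone; adjusted p = 0.00151, and adjusted p = 0.0914 with an estimated correlation). In islet, liver and muscle edgeR called 0 regions, with 1523, 971 and 134 at an unadjusted p under 0.05, and DESeq2 called 0, 12 and 0.

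Strain changed detection far more than sex or diet. It changed 43927 of 70290 adipose regions (62.5%), 56687 of 76015 islet regions (74.6%), 29125 of 48439 liver regions (60.1%) and 8734 of 41132 muscle regions (21.2%). Without the doubted libraries the counts were 43455, 54890, 28773 and 9164. Library runs are unbalanced over strains; with the run in the model 76.5% of the calls were left in adipose, 77.4% in islet, 73.5% in liver and 55.9% in muscle. A region inside the agouti gene a (2:155018558-155020288), which sets coat colour, was detected in adipose of all 12 A/J, C57BL/6J, CAST/EiJ, NOD/ShiLtJ and PWK/PhJ animals and in 0 of the NZO/HlLtJ, WSB/EiJ and the eighth strain's animals. In liver, a region of Stab2 (10:86989848-86991416) was detected in 0 of 13 WSB/EiJ libraries, 11 of 12 CAST/EiJ and 12 of 12 libraries of each other strain. In islet, a region of Vipr2 (12:116095652-116097248), which encodes a neuropeptide receptor that raises insulin release, was detected in 0 of 12 libraries of the eighth strain and 12 of 12 libraries of each other strain. A region 26208 bp from Kcmf1 (6:72926187-72927639) was absent from A/J libraries in adipose, islet and muscle. A region inside Tmem267 (13:119494490-119495270) was detected in NOD/ShiLtJ alone in adipose and muscle, in 12 of 12 libraries. Regions with the highest F statistics that are not described here include those near Defa21 in adipose, H60b in liver and Vmn2r87 in muscle, and inside Umad1 in islet. Peaks of all strains are placed on the same reference. Whether such all-or-none patterns reflect chromatin, mapping or sequence differences between strains was not tested for these regions.

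CAST/EiJ and PWK/PhJ, both wild-derived, had the most regions at least 50% of libraries away from the mean of the other strains in islet (8471 and 10633) and liver (4291 and 3322), and PWK/PhJ had the most in muscle (803). In adipose NZO/HlLtJ had the most, 7050, of which 21.7% were lower, followed by CAST/EiJ with 6386, of which 65.8% were lower. With the run in the model 51.0% of the NZO/HlLtJ regions were still called with the same sign, against 99.4% of those of CAST/EiJ, and CAST/EiJ then had the most in adipose (7501, against 5423 in NZO/HlLtJ). In liver WSB/EiJ then had more such regions (4276) than PWK/PhJ (3219). The smallest of these counts was 120, in muscle of the eighth strain. Of the regions that differed in CAST/EiJ, 3549 did so in the same direction in adipose and liver, against 1630 by chance.

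**Figure D4:**
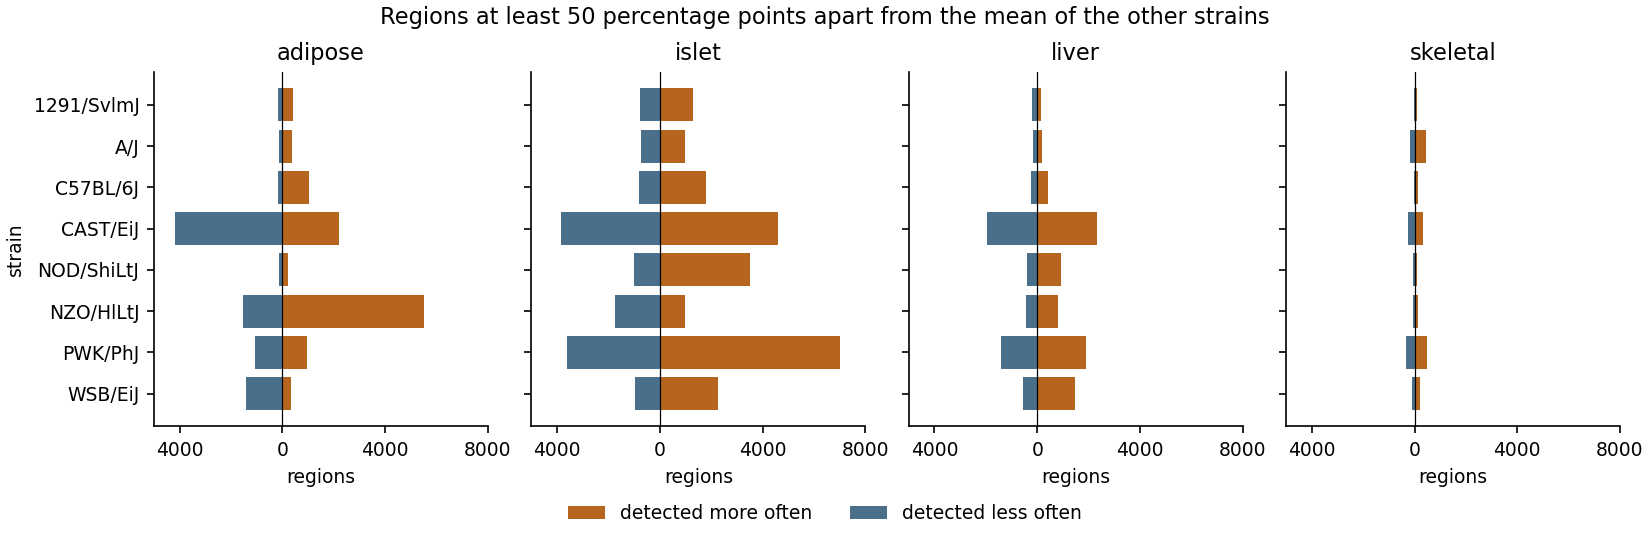
Number of regions detected at least 50 percentage points more or less often in a strain than in the mean of the other strains, for 8 strains in 4 tissues. NZO/HlLtJ had 7050 in adipose and PWK/PhJ 10633 in islet.

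Genes of inflammation and lysosomes in obese fat differed between strains in adipose with the preset correlation only. The list tests by strain left out the library run. Of the 12 NZO/HlLtJ adipose libraries 11 fell in 1 run, so strain and run are hard to tell apart there. In NZO/HlLtJ 68 of 127 inflammation regions were higher and 2 lower (74 and 4 adjusted over the list alone; camera adjusted p = 2.43e-08, and adjusted p = 0.134 with an estimated correlation). In CAST/EiJ 4 were higher and 63 lower (6 and 69 adjusted over the list alone; adjusted p = 2.76e-06, and adjusted p = 0.138 with an estimated correlation). In WSB/EiJ 1 was higher and 33 lower (2 and 40 adjusted over the list alone; adjusted p = 0.000587, and adjusted p = 0.403 with an estimated correlation). In A/J 8 were higher and 0 lower (13 and 0 adjusted over the list alone, adjusted p = 0.0108, and adjusted p = 0.53 with an estimated correlation). In PWK/PhJ 5 were higher and 14 lower (5 and 19 adjusted over the list alone, adjusted p = 0.0206, and adjusted p = 0.837 with an estimated correlation). Mesothelial genes went the other way, with 2 of 30 regions higher and 11 lower in NZO/HlLtJ (3 and 14 adjusted over the list alone, adjusted p = 0.00493, and adjusted p = 0.134 with an estimated correlation). In CAST/EiJ 12 were higher and 3 lower (13 and 3 adjusted over the list alone, adjusted p = 0.0033, and adjusted p = 0.138 with an estimated correlation). The macrophage list went the way of the inflammation list in adipose, with 32 of 84 regions higher and 8 lower in NZO/HlLtJ (36 and 8 adjusted over the list alone, adjusted p = 0.398 with an estimated correlation). In CAST/EiJ 4 were higher and 44 lower (5 and 46 adjusted over the list alone, adjusted p = 0.138 with an estimated correlation). The adipose macrophage share was 0.689 ± 0.0579 in C57BL/6J, whose list was not called, 0.667 ± 0.0576 in NZO/HlLtJ and 0.452 ± 0.139 in CAST/EiJ (SD, n = 12 each). In A/J muscle, 8 of 38 macrophage regions were higher (12 adjusted over the list alone), which held with an estimated correlation (adjusted p = 0.0112). Of the 11 A/J muscle libraries, 2 are among the doubted ones, with lymphocyte shares of 0.789 and 0.684, and the list was not tested without them. In C57BL/6J, X-inactivation and escape genes were higher with an estimated correlation in muscle (4 of 16 regions; 4 adjusted over the list alone; adjusted p = 0.00099), adipose (7 of 22 higher and 1 lower; 11 and 2 adjusted over the list alone; adjusted p = 0.0115) and liver (6 of 25 higher and 1 lower; 6 and 3 adjusted over the list alone; adjusted p = 0.0483), where their median difference was negative and their mean positive. In NOD/ShiLtJ muscle, skeletal myofibre genes were lower with an estimated correlation (0 of 15 regions higher and 1 lower, 0 and 3 adjusted over the list alone, adjusted p = 0.0137), with 6.67% of the differences positive. Of 36 list calls by strain 5 held with an estimated correlation.

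Diet effects that differed between strains were called at 255 adipose, 168 islet, 138 liver and 0 muscle regions (182, 98, 47 and 0 without the doubted libraries; 2291 at an unadjusted p under 0.05 in muscle). In adipose, a region at Snx30 (4:59821754-59822470) went from 0 of 6 C57BL/6J libraries at 10% fat to 5 of 6 at 44%, and from 4 to 0 in NZO/HlLtJ (adjusted p = 9.5e-07). In islet, a region near Dtnb (12:3557365-3558504) went from 6 to 1 of 6 NZO/HlLtJ libraries (adjusted p = 4.5e-09), and one near the nicotinamide methyltransferase gene Nnmt (9:48520563-48522108) from 4 to 0, while PWK/PhJ had it in 6 of 6 on both diets. Diet effects that differed between the sexes were called at 0 adipose, 0 islet and 0 muscle regions (6605, 4667 and 2024 at an unadjusted p under 0.05) and 1 liver region, near the adhesion molecule gene Vcam1 (3:116161962-116162732; adjusted p = 0.0331). It was detected in 8 and 12 of 24 female libraries at 10% and 44% fat, and in 16 of 25 and 3 of 24 male libraries. This call was lost (0 regions) without the doubted libraries, and without the library run in the model.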

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

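Chosen only after the results were seen were the test of sex differences between tissues, the test of scarce hepatocytes, the test without the 2 liver libraries out of place by their Y chromosome regions, the counts without doubted libraries, and the tests of mapping and of library run for the strains, the latter refitted on the CAST/EiJ and PWK/PhJ regions.

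A difference between groups was found for the effect of diet in strains, at 255 adipose, 168 islet and 138 liver regions, and for the effect of diet in the sexes, at 1 liver region, near Vcam1. For adipose, 4 of 100 regroupings of the libraries gave as many regions with a strain by diet difference, the real one included, and the highest other count was 592. This is under the 0.05 level, but without correction over the 4 tissues, so chance is not firmly excluded. At an unadjusted p under 0.05, 6 of 100 reached the 7071 regions of the real grouping (highest other 9804), so for that count chance is not excluded. For liver it was 2 of 100, with a highest other count of 361, and 1 of 100 for the 5243 regions at an unadjusted p under 0.05 (highest other 4801). For islet, 27 of 100 regroupings gave as many (highest other 521), and chance cannot be excluded. What gives such high counts after regrouping was not tested, so single regions such as those at Snx30 or Dtnb are hypotheses. In muscle 0 regions were called by limma (2291 at an unadjusted p under 0.05), which all 100 of 100 regroupings reach by construction, with a highest other count of 9; the 2291 were reached by 42 of 100. For the Vcam1 region, 5 of 100 regroupings gave as many, with a highest other count of 1, so chance cannot be excluded. The 2320 liver regions at an unadjusted p under 0.05 were reached by 57 of 100. In adipose, islet and muscle limma called 0 such regions (6605, 4667 and 2024 at an unadjusted p under 0.05), which all 100 of 100 regroupings reach by construction, with highest other counts of 1, 1 and 8. The counts at an unadjusted p were reached by 3 of 100 regroupings in adipose (highest other 7027), 13 in islet and 44 in muscle, so in adipose more regions had a small p than in most regroupings, though limma called none of them.

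A test of whether the effect of sex differs between tissues called 12516 of 174877 regions. Of these, 11814 were autosomal, 692 on X and 10 on Y. The test holds the peak number within each tissue but not the library run. Within tissues, fewer regions were called by sex: 3400 of 70290 tested in adipose and 153 of 76015 in islet. In liver 166 of 48439 were called, and in muscle 104 of 41132. The test between tissues thus includes regions that varied too little in some tissues to be tested there. The libraries were not regrouped for this count, so chance is not excluded and the size of the count stays uncertain. What would cause a difference between tissues was not tested.

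The first pattern weighed is that hepatocyte regions were seldom detected in liver, where the gene end share was 0.184 ± 0.0694 (SD, n = 97). Too few peaks is argued against. The 51 liver libraries with at least as many peaks as the poorest islet library had 17.4% ± 3.49 (SD) of all hepatocyte-linked regions. Islet libraries had 43.5% ± 7.97 (SD, n = 96). Scarce hepatocytes among the transposed cells may explain it, but the marker shares cannot decide this. The endothelial, macrophage and lymphocyte shares all exceeded the hepatocyte share in 98.97% of the liver libraries (96 of 97). The mean shares were known before that test was set, and shares of different lists do not measure cell numbers. The white adipocyte share in liver was as high as 0.756 ± 0.0861 (SD, n = 97). The liver was dissociated to a suspension that was frozen, a step that may favour small cells, but the loss at that step was not tested. Why islet libraries had more hepatocyte regions, among them those of Alb, Cps1 and Tat, was not tested.

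The second pattern is that read counts of 835 autosomal liver regions differed by sex, with endothelial regions such as Kdr and Tek lower in females. A different mix of endothelial and immune cells in the suspensions of the sexes is a candidate explanation: with scores of both cell groups as covariates, 0.479% of the calls were left, as the median size of the called log2 differences went from 0.22 (median SE 0.066) to 0.05 (median SE 0.048). The mean endothelial score was 5.15 ± 0.258 (SD, n = 48) in females and 5.37 ± 0.338 (SD, n = 49) in males. The mean immune score went the other way, 5.46 ± 0.206 in females and 5.36 ± 0.187 in males (SD, same libraries). Whether the mix differs in the living liver was not tested. The test has limits: the endothelial score is the mean of 17 list regions, of which 10 were themselves called lower in females, and the scores also took the X calls from 45 to 20, which a cell mix need not explain. The 2 libraries out of place by their Y regions are argued against, since 98.4% of the calls were left without them. Library run was weighed too. With the run held 880 regions were called, 45 of them on X. Regrouped libraries gave at most 136 with the run held, which bears on chance rather than on the run. Without the run 2558 were called, so the run does move calls. That the model with the run left these calls follows from how they were chosen. Within the 2 largest runs, 99.8% (13 female and 10 male libraries) and 84.4% (7 and 10) of the calls had the same sign. The regions were called in a fit that holds these same libraries, so high shares are partly built in. The share of 84.4% misses the bound set before the test, so the part played by the run stays open.

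The third pattern is that the wild-derived strains CAST/EiJ and PWK/PhJ had many regions at least 50% of libraries away from the other strains, the most of all strains in islet and liver. If reads of strains far from the reference map worse and peaks are lost, this cannot be the whole cause, since in PWK/PhJ islet only 34.1% of those regions were lower. For the regions that were lower, mapping loss stays open: the percentage lower exceeded that in A/J, NOD/ShiLtJ, NZO/HlLtJ and the eighth strain for both strains in 2 of 4 tissues, but in adipose, 1 of the 2, it was higher still in wild-derived WSB/EiJ (80.6%). Library run as the whole cause is argued against, since at least 71.4% of these CAST/EiJ and PWK/PhJ regions in each tissue were called with the same sign with the run in the model. Sequence differences in regulatory regions may explain the rest, and no genotypes were used to test it.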

How the results depend on the processing

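Chosen after seeing the data were the alternatives without doubted libraries and the lists in read counts. The estimated correlation was planned as a test beside the preset one and added to the alternatives after seeing the data, and the others were planned. Of 330 alternatives of 39 counts, 219 stayed within 1.5 times and 111 moved. Of 3765 alternatives of 382 named regions, 2877 kept direction and side of the threshold, 872 fell short of it and 16 reversed. The animal block kept all 20 tissue regions it was run on, and DESeq2 all 138 read-count regions. The filter on low counts removed 0 regions, so leaving it out tests nothing. Replicate 4 exists in few groups and not in islet.

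With the 15000 strongest peaks per library, restricted regions numbered 22 in adipose, 4993 in islet, 1023 in liver and 250 in skeletal. Sex counts were 158 in adipose, 40 in islet and 25 in skeletal. Diet in adipose gave 2. Strain gave 7948, 11741, 7003 and 3.9e+03. Sex by diet in liver gave 0, and strain by diet 96 in islet and 25 in liver. Fewer regions can be detected in that setting, by construction. Why restricted skeletal regions rose instead, from 37 to 250, was not tested.

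With an overlap of 0.5 of the region, diet in adipose gave 7, strain in skeletal 5003, restricted liver 1528 and restricted skeletal 9. With the stricter threshold, sex in islet gave 91, diet in adipose 0 and restricted skeletal 18. With regions from at least 30 libraries, sex in islet gave 98. The Cochran-Mantel-Haenszel test gave 18160 for sex in adipose, 50 in skeletal and 0 for diet in adipose; it does not hold the peak number, which differs by sex in adipose. Without the peak number in the model, sex gave 7744 in adipose and 49 in skeletal.

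Without the library run, sex gave 243 in islet, 666 in liver and 372 in skeletal, diet in adipose 5, sex by diet in liver 0 and strain by diet in adipose 618; read counts by sex gave 3653 in adipose, 4411 in islet, 2558 in liver and 178 in skeletal, and by diet in liver 1. With the run, strain in skeletal gave 5444. The cause was not tested. Without the doubted libraries, sex by diet in liver gave 0, strain by diet 98 in islet and 47 in liver, and read counts by sex 1376 in liver.

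For read counts, the offset for covered length gave 448, 113, 1420 and 7 by sex in adipose, islet, liver and skeletal, and 76 and 9 by diet in adipose and liver. DESeq2 gave 166 by diet in adipose and 12 in liver. The cause was not tested. With an estimated correlation, the lists called numbered 0 by diet in detection and 0 in read counts, 5 by sex in detection and 4 in read counts, 5 by strain and 2 by tissue. With links within 10 kb they numbered 2 by diet in detection and 0 in read counts.

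Leaving out 1 replicate number at a time removes many libraries, and counts ranged as follows. Sex gave 818 to 3407 in adipose, 52 to 79 in islet, 40 to 165 in liver and 28 to 104 in skeletal. Diet in adipose gave 0 to 12. Strain gave 25022 to 44005 in adipose, 37176 to 38485 in islet, 16988 to 28822 in liver and 2184 to 8496 in skeletal. Sex by diet in liver gave 0 to 1. Strain by diet gave 0 to 253 in adipose, 34 to 101 in islet and 0 to 136 in liver. Read counts by sex gave 342 to 1805 in adipose, 25 to 180 in islet, 19 to 957 in liver and 8 to 24 in skeletal, and by diet 0 to 29 in adipose. Restricted skeletal regions gave 18 to 63.

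These regions reversed. With an overlap of 0.5, sex differences became 0.0184 for Rpl3 in islet, -0.0566 for Per2 in adipose and 0.0830 for Slc2a2 in skeletal, as shares. Per2 became -0.115 by the Cochran-Mantel-Haenszel test, and St3gal4 in liver 0.0294 with the stricter threshold. With the offset for covered length, log2 sex differences became 0.0303 for Cd109, -0.0182 for Stard4, -0.0114 for Elovl6, 0.135 for Cd68, -0.00922 for Bcl6 and 0.00243 for Cebpa in adipose, 0.0749 for Pdx1, 0.0433 for Trim27 and 0.0214 for Zmiz1 in islet, and -0.0107 for Ptprc in liver. The log2 diet difference of Ninj2 in adipose became -0.0533. The cause was not tested.

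Skeletal libraries had the fewest peaks and reads. The simulations, run on liver libraries, recovered 13 of 67 sex differences of 0.3 in detection, and none was run for skeletal libraries.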

Other observations

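The islet tests by strain and diet and the counts without doubted libraries were chosen only after the results were seen, while the regroupings were planned.

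Regroupings of the libraries showed which counts chance can give. For restricted regions, 1 of 21 groupings, the real one, gave as many in each tissue (1001 in adipose, 26015 in islet, 2534 in liver and 37 in muscle, with 0 as the highest other count). For sex in detection, 1 of 100 groupings, the real one, gave as many: 3400 against a highest other count of 145 in adipose, 153 against 1 in islet, 166 against 1 in liver and 104 against 40 in muscle. For strain, 1 of 100, the real one, gave as many: 43927 against 2 in adipose, 56687 against 135 in islet, 29125 against 16 in liver and 8734 against 537 in muscle. For diet in adipose, 1 of 100, the real one, gave as many, 12 regions against a highest other count of 3. For these counts as totals chance is excluded at the 0.05 level. For sex in muscle this does not hold at an unadjusted p under 0.05. There 7 of 100 groupings reached the 3370 regions of the real one (highest other 8272). The sex totals include X and Y regions, for which a difference is partly built in. Autosomal calls alone numbered 3255 in adipose, 31 in islet, 90 in liver and 68 in muscle. These are above the highest other totals, but they were adjusted together with the X and Y regions. Autosomal regions were not regrouped apart, so for them chance is not firmly excluded. For diet in islet, liver and muscle, where limma called 0 regions (4466, 2319 and 1509 at an unadjusted p under 0.05), all 100 of 100 groupings reach that by construction, with highest other counts of 1, 1 and 2, and the counts at an unadjusted p were reached by 15, 53 and 79 of 100.

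For read counts by sex, 1 of 21 groupings, the real one, gave as many, and the highest other counts were 0 in adipose (1804 in the real one), 0 in islet (507 higher and 219 lower), 136 in liver (880) and 0 in muscle (24). This is under the 0.05 level, but without correction over the 4 tissues, so chance is not firmly excluded. The counts include X regions, 20 of the 24 in muscle, and autosomal regions were not regrouped apart. Leaving out a replicate number could lower the islet and liver counts strongly, as given above. For read counts by diet in adipose, 2 of 21 groupings gave as many as the 29 regions, with a highest other count of 67, so chance cannot be excluded and the regions at Has1 and Cxcl1 are hypotheses. In islet, liver and muscle edgeR called 0 (1523, 971 and 134 at an unadjusted p under 0.05), which all 21 of 21 groupings reach by construction, with highest other counts of 0, 0 and 1.

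In adipose the scores of endothelial and immune regions left more of the autosomal read count calls by sex than in liver, 73.9% (1229 of 1662 called in both), and in islet 44.5%. Whether these shares differ was not tested. With the scores, the median size of the called log2 differences went from 0.167 (median SE 0.046) to 0.152 (0.044) in adipose. In islet it went from 0.195 (0.053) to 0.147 (0.047).

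In NZO/HlLtJ islets, the beta cell share was 0.681 ± 0.142 at 44% fat and 0.775 ± 0.0578 at 10% (SD, n = 6 each; exact permutation p = 0.21), and the acinar share 0.478 ± 0.361 and 0.244 ± 0.0807 (SD, n = 6 each; exact permutation p = 0.203). The former group holds the 2 doubted islet libraries. Of 24 such tests, the lowest adjusted p was 0.93.

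The epididymal and ovarian duct share in adipose was 0.20 ± 0.080 (SD, n = 48) in female and 0.314 ± 0.188 (SD, n = 49) in male libraries, and the mesothelial share was 0.792 in CAST/EiJ.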
